A study of Homo sapiens with 12 samples.

How the data were processed

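The data are a single table of transcript abundance for 12 RNA-seq libraries of A549 cells in 4 groups of 3: NR0B1 overexpression, its control, NR0B1 knockdown and its control. The authors deposited, for each library, expected counts and FPKM values per transcript, as the column names of the table show. Per the submitters' processing notes, fastp, HISAT2 2.0.5, Bowtie2 2.2.8, StringTie 1.3.1 and RSEM were used; fractional expected counts as in the table are what RSEM gives, and FPKM values are the authors' own, scaled to transcript length and library size. The same notes name the mouse builds GRCm38 and mm10, whereas the transcript identifiers are human, so no build was taken from the notes. Filters, the annotation release and whether counting used strand are not given in the sources used here; without strand, reads of a gene and of an overlapping antisense gene cannot be told apart.

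The table has 96247 rows. Of these, 82270 carry Ensembl transcript identifiers, 82237 of which are in GENCODE 29 (GRCh38), with the same gene symbol for 99.78%. All coordinates come from that annotation. The other 13977 rows are assembled transcripts with a TCONS identifier that hold between 13.3% and 15.4% of the expected counts; they were left out of gene values because their symbols rest on similarity alone, and are given separately in the closing section. In 184 rows the symbol had been turned into a date, and all 184 were restored from the transcript identifier. Expected counts and FPKM were summed over the Ensembl transcripts of each gene, giving 19647 genes, and sums of expected counts were rounded to whole numbers. Libraries held between 15049011 and 22797076 expected counts. A gene with 3 counts in a library stands at between 0.155 and 0.235 CPM, which is the floor used here for a gene at 0. For a group whose 3 libraries are all at 0, a fold is given as a lower bound against 3 counts over the group. Such floors cover counting error only, since PCR copies are not independent molecules. 

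Genes with an FPKM of 1 or more in at least 3 of the 12 libraries were tested, 11908 in all. The tests were planned on the assumption of FPKM values only, with limma on log2(FPKM + 1); the table also held expected counts, so edgeR 4.0.16 (glmQLFit and glmQLFTest, robust, TMM scaling) in R 4.3.3 is the main test, as the plan foresaw, and limma 3.58.1 on FPKM is an alternative. A fold change on the log2(FPKM + 1) scale understates the change of low genes. All 12 libraries entered a single fit with a mean per group and no covariate, leaving 8 residual degrees of freedom. The contrasts were overexpression minus its control, knockdown minus its control, the difference of these, and the control groups against each other. The difference of the arms tests whether the responses differ and does not require that both pass. A gene was called at an adjusted p below 0.05 (Benjamini-Hochberg), and the biological coefficient of variation was 24.5%. CPM are counts scaled to TMM-adjusted library size.

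Before the data were examined, 39 gene lists were written from textbook knowledge, of which 36 had at least 3 measured genes. They were tested with camera on log2(FPKM + 1) with a preset correlation of 0.01, adjusted over the 36 lists. With an estimated correlation 0 lists were called in any comparison. Counts of list members that passed are given over all genes tested and adjusted over the list alone. They are to be read beside the share of all genes tested that were called, 18.1% with overexpression and 23.9% in the knockdown. Such counts depend on the setting: of the counts above 0, 39 of 52 with overexpression and 40 of 54 in the knockdown moved by more than 1.5 times in at least 1 of 7 other settings, of which the omission of both libraries that stand apart was chosen after seeing the data.

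The genes named in the text follow a rule fixed beforehand: NR0B1 and the study focus genes; the 8 largest rises and 8 largest falls among called genes with a mean FPKM of 1 or more in the higher group and no overlap between the 3 treated and 3 control libraries; up to 4 called members of each described list with the smallest adjusted p, or 2 with the highest mean FPKM where none passed; and across the arms up to 8 genes called in opposite directions and 4 called in the same direction, by the smaller of their absolute fold changes. Not every gene that this rule takes is named. Genes known only by a clone name were passed over, and HMOX1, ACSF2 with overexpression, FOS, DUSP4, MBOAT2, AKR1C1, CD14, NEFL, INA and SOX2 were added after their values were seen, to complete small counts. By chance, 10% of genes would show no overlap between 3 and 3 libraries.

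The fit was tested on simulated data: counts for 11908 genes were drawn with 200 genes changed in each comparison. At 1.5-fold, 2-fold and 4-fold, 6.1%, 58.2% and 91% of changed genes were recovered for overexpression and 7.6%, 53.7% and 86.6% for the knockdown, with 5 and 3 false calls. camera called the shifted list and 0 of the other simulated lists. The real lists had a median estimated correlation between genes of 0.142, with values up to 0.957. The simulation did not model such correlation, so it cannot show how often camera calls a real list without a true shift. It also drew each gene independently, with far fewer genes changed than the 2152 and 2851 called in the data. Its recovery and false calls therefore need not hold for these data.

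The alternatives were another pseudocount, no filter and a stricter filter, median-of-ratios scaling, quantile normalization, fitting only the 6 libraries of an arm, a replicate block, a prior without trend, DESeq2 1.42.0, leaving out each library in turn, and an estimated correlation for camera. Added after seeing the data were the removal of both libraries that stand apart from their group, the assembled rows as features of their own, camera on log2 CPM, and a test of 279 pathways from the annotation column of the deposited table. Other splits of the libraries (10 for each comparison of 6, and 100 drawn for both arms) were fitted in the same way. Single genes in NR0B1's comparison were also tested by exact permutation, two-sided.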

Results

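RNA sequencing measured transcript abundance in 12 libraries of A549 cells, a human lung adenocarcinoma line whose KEAP1 gene is mutated so that the oxidative stress regulator NRF2 is active. The series has 4 groups of 3 libraries: cells overexpressing NR0B1, their control, cells with a short hairpin RNA against NR0B1, and the control of that knockdown. NR0B1, also called DAX1, is an orphan nuclear receptor that acts mainly as a repressor of transcription. Each library started from 3 µg of RNA, per the labels, and held between 15049011 and 22797076 expected counts. Values are CPM, counts scaled to library size, as mean ± SD with n = 3 libraries per group. Log2 fold changes carry an approximate standard error (SE), the absolute log2 fold change divided by the square root of the test's F statistic. It is unreliable at low counts. Adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 11908 genes. They measure the spread between these samples only, since the labels do not say that replicates were separate cultures.

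NR0B1 itself was examined first in every library, because it checks the labels. The gene (ENSG00000169297) lies on chromosome X from 30304206 to 30309598 on the minus strand in GRCh38, and 2 of its transcripts are in the data. In the overexpression libraries NR0B1 stood at 98.9, 81.8 and 84.1 CPM, against 17.9, 60.1 and 55.2 CPM in replicates 1 to 3 of their control. The means were 88.3 ± 9.31 and 44.4 ± 23.1 CPM, a log2 fold change of 0.99 (SE 0.38) that did not pass the test (adjusted p = 0.0912). Control replicate 1 lay far below the other controls, and without it the log2 difference was 0.62 (adjusted p = 0.106). limma on log2(FPKM + 1) gave an adjusted p of 0.0452 and DESeq2 0.0415, in a range of 0.0415 to 0.199 over the alternatives. In the knockdown NR0B1 fell 4.18-fold, from 16.9 ± 3.95 to 4.05 ± 1.56 CPM (log2 fold change -2.06, SE 0.42, adjusted p = 0.00593), with 2.99, 3.31 and 5.84 CPM in its replicates. The 2 controls differed as well: NR0B1 was 2.63-fold higher in the overexpression control than in the knockdown control (log2 difference 1.40, SE 0.39, adjusted p = 0.0189), but their ranges overlapped (exact permutation p = 0.3), since overexpression control replicate 1 lay within the 13.3 to 21.1 CPM of the knockdown control. The overexpression and knockdown libraries did not overlap with their own controls, for which a two-sided exact permutation test on FPKM gave p = 0.1 in each arm, the smallest value that 3 against 3 libraries allow.

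**Figure D1:**
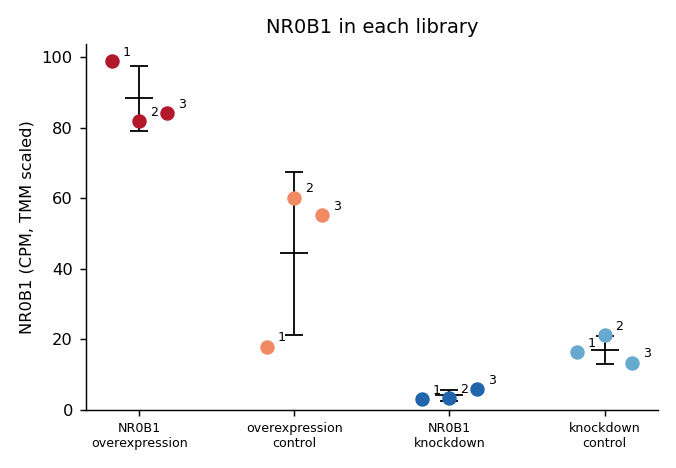
NR0B1 in CPM (vertical axis, linear from 0) in each of the 12 libraries, with dots numbered by replicate and bars for the mean and SD of each group. The overexpression libraries sit between 81.8 and 98.9 CPM and the knockdown libraries between 2.99 and 5.84 CPM, while the overexpression control spans 17.9 to 60.1 CPM.

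The overexpression arm asks which transcripts change when NR0B1 is raised, with glutathione metabolism and ferroptosis, an iron-dependent form of cell death driven by lipid peroxidation, named in the title of the series. The connective tissue growth factor CTGF rose 9.53-fold, from 20.4 ± 2.0 to 194 ± 18 CPM (adjusted p = 6e-06), and the AP-1 subunit JUN rose 5.75-fold, from 49.3 ± 16.9 to 284 ± 11.9 CPM (log2 fold change 2.52, SE 0.22, adjusted p = 0.000212). The glutathione peroxidase GPX4, which reduces lipid peroxides, fell 1.70-fold from 169 ± 16.2 to 99 ± 4.79 CPM. In all, 2152 genes passed the threshold, 1175 higher and 977 lower, and 565 of them differed by 2-fold or more (344 higher and 221 lower). The latter count ran from 344 to 893 when each library was left out in turn, and was 348 with limma.

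The largest rises included NR4A3, a nuclear receptor of the immediate early class, which went from 2.08 ± 0.632 to 72.0 ± 12 CPM (log2 fold change 5.11, SE 0.37, adjusted p = 5.31e-05). The thyroid hormone deiodinase DIO2 reached 32.7 ± 7.46 CPM from 0.382 ± 0.661 CPM, the zinc finger factor EGR3 13.2 ± 1.95 from 0.231 ± 0.252 CPM, and the AP-1 subunit FOSB 76.4 ± 11.9 from 4.11 ± 0.868 CPM. ANKRD1, a target of YAP signalling, rose 16.1-fold to 81.4 ± 10.1 CPM, and the BMP antagonist GREM1 rose 11.7-fold to 43.3 ± 5.24 CPM. PLGLB1, which shares its sequence with PLGLB2, and NOP56 were also among the 8 largest rises, at 1.72 ± 0.632 and 1.98 ± 0.760 CPM, and both are uncertain. TMEM265 was at 0 in the 3 overexpression libraries and at 3.76 ± 0.951 CPM in the control, at least 51.9-fold lower against a floor of 3 counts over the group. Further large falls were those of the adaptor GRB7 (25.2 ± 11.1 to 1.90 ± 1.65 CPM), the cytokine signalling inhibitor CISH (log2 fold change -3.0, SE 0.43) and the semaphorin SEMA4C (-2.97, SE 0.76). They also included the cadherin CDH16 (-2.85, SE 0.55), ABHD8 (-2.59, SE 0.63), the cytokine IL1B (-2.51, SE 0.78) and ZNF823 (-2.49, SE 0.47). The calls of TMEM265, GRB7, SEMA4C, ABHD8, IL1B and NOP56 ended without any 1 of between 2 and 9 libraries, drawn from overexpression replicates 1 to 3 and control replicates 2 and 3 and, for IL1B, also control replicate 1 and the knockdown controls, with adjusted p-values up to 0.131 for IL1B without overexpression replicate 2. The highest was 0.0866 for TMEM265 without replicate 3, 0.0849 for SEMA4C without replicate 2, 0.078 for ABHD8 without replicate 3, and 0.0654 for GRB7 and 0.069 for NOP56 without control replicates 3 and 2.

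Of the 11 study focus genes, fixed beforehand, 3 rose and 2 fell in the overexpression arm over all genes tested, and 5 rose and 2 fell adjusted over the list alone; without control replicate 1, 6 rose and 2 fell. CBS, JUN and NFE2L2 were put on this list because the study is known to have followed them up, so the list is not independent evidence of its direction. CBS, the enzyme that makes cystathionine from homocysteine (ENSG00000160200, chromosome 21 from 43053191 to 43076943 in GRCh38), rose 1.75-fold from 24.0 ± 7.37 to 41.9 ± 6.0 CPM (log2 fold change 0.80, SE 0.24, adjusted p = 0.0394). Reads of CBS can be shared with its near-identical copy CBSL, and its call ended without any of the overexpression replicates 1 to 3 (adjusted p of 0.0678, 0.0718 and 0.122), control replicates 2 and 3 (0.121 and 0.131), or knockdown control replicates 1 to 3 (0.0522, 0.0523 and 0.0509). KEAP1, the adaptor that targets NRF2 for degradation, rose 1.63-fold (adjusted p = 0.0186, and 0.073 without control replicate 3), and the glutathione synthetase GSS fell by 0.31 on the log2 scale (adjusted p = 0.0341, and 0.149 without overexpression replicate 3). The call of KEAP1 ended without any 1 of 3 libraries. That of GSS ended without any 1 of 7, namely overexpression replicates 1 to 3, control replicate 2 and the knockdown controls. NFE2L2, which encodes NRF2, was at 289 ± 20.6 against 200 ± 39.1 CPM and did not pass (adjusted p = 0.0606), although it passed at 0.0207, 0.0491 and 0.0106 without control replicate 1 and knockdown replicates 1 and 2. The cystine transporter SLC7A11 showed 1050, 314 and 300 CPM in control replicates 1 to 3 and 809, 586 and 739 CPM with overexpression (adjusted p = 0.568, and 0.00282 without control replicate 1). GCLC, GCLM and GSR did not pass, at log2 differences of 0.44, 0.45 and -0.14, though GCLC passed without control replicate 1 (0.0466) and GCLM without knockdown replicate 3 (0.046), and GSR stood at 0.03 without control replicate 1.

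**Figure D2:**
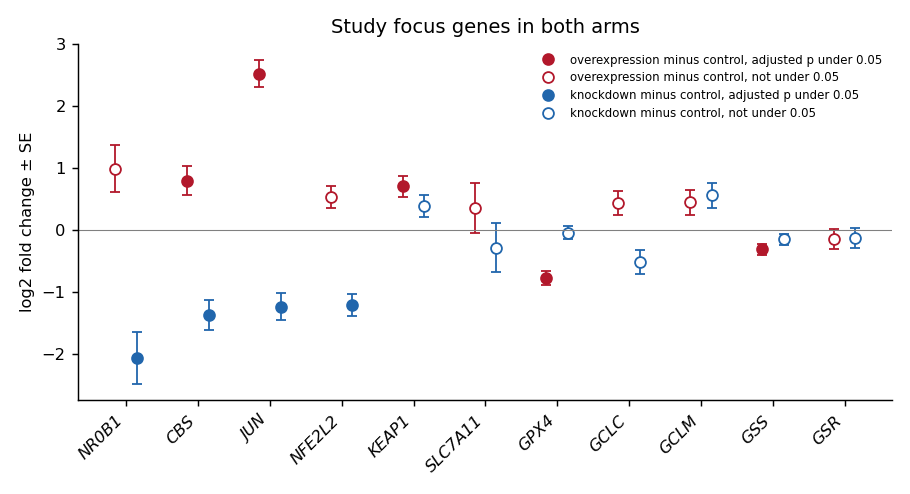
Log2 fold change ± SE (vertical axis) of the 11 study focus genes against the control of their own arm, with overexpression in red and knockdown in blue. Filled dots passed an adjusted p of 0.05, as JUN did at 2.52 in the overexpression arm and at -1.23 in the knockdown.

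Of 43 measured glutathione metabolism genes, 1 rose and 10 fell, and adjusted over the list alone 1 rose and 14 fell. camera called the list lower (adjusted p = 0.0187), a call lost with an estimated correlation (adjusted p = 0.501 with an estimated correlation) and without control replicate 1 (0.2), where 4 rose and 9 fell. Besides GPX4 at a log2 fold change of -0.77 (SE 0.11), GPX1 fell to 137 ± 0.599 from 210 ± 10.5 CPM and the microsomal transferase MGST3 to 53 ± 3.43 from 76.7 ± 4.12 CPM. ODC1, the first enzyme of polyamine synthesis, was the member that rose, to 141 ± 11.7 from 73.6 ± 17.9 CPM. Among 30 ferroptosis suppressors 1 rose and 4 fell (0 and 4 adjusted over the list alone), and camera did not call the list (adjusted p = 0.248). Without control replicate 1, 6 rose and 4 fell. The member that rose was the heme oxygenase HMOX1 (log2 fold change 1.14, adjusted p = 0.0497). Its falling members were GPX4, the small heat shock protein HSPB1 (159 ± 3.36 from 258 ± 32.1 CPM) and the aldo-keto reductases AKR1C3 and AKR1C2, close paralogs whose shared reads make them uncertain. Among 27 ferroptosis drivers 1 rose and 4 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.181; 1 and 7 without knockdown replicate 2): KEAP1 was the member that rose, and the polyamine acetyltransferase SAT1 fell 4.54-fold to 45.6 ± 2.78 CPM, followed by the iron transporter SLC11A2 (1.72-fold), the lipoxygenase ALOX5 (5.59-fold) and ACSF2 (log2 fold change -0.86). Of 37 NRF2 targets 2 rose and 7 fell (2 and 8 adjusted over the list alone, camera adjusted p = 0.109; 5 and 5 without control replicate 1), with OSGIN1 up 6.79-fold to 126 ± 9.91 CPM and the pentose phosphate enzymes TKT and TALDO1 down 1.55-fold and 1.45-fold. Over all genes tested 18.1% were called with overexpression, and the called members of the ferroptosis suppressor and driver lists lay near that share. Calls of ODC1, HSPB1, AKR1C2, SLC11A2, ALOX5, TKT and TALDO1 ended without any 1 of between 1 and 7 libraries of this arm or, for AKR1C2, the knockdown controls. The highest adjusted p was 0.069 for ODC1 without control replicate 2, 0.0636 for HSPB1, 0.0634 for TKT, 0.0501 for SLC11A2 and 0.059 for ALOX5 without overexpression replicate 3, and 0.123 for AKR1C2 and 0.0884 for TALDO1 without overexpression replicate 2.

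AP-1 and immediate early genes rose in the overexpression arm: 10 of 23 were higher and 0 lower (12 and 0 adjusted over the list alone), with camera at an adjusted p of 0.000363, and adjusted p = 0.501 with an estimated correlation. MYC was among them, at 303 ± 10.4 against 77.1 ± 12.8 CPM. Of 29 TGF-beta and EMT genes 8 rose and 1 fell (8 and 1 adjusted over the list alone), with camera at 0.0147 and adjusted p = 0.501 with an estimated correlation. CTGF had the smallest adjusted p of this list, ANKRD1 the largest rise, and the inhibitory SMAD7 rose 5.14-fold and the transcription factor SNAI2 7.16-fold. In the knockdown 10 of these 29 genes rose and 3 fell (11 and 4 adjusted over the list alone). There camera did not call the list (adjusted p = 0.113). COL1A1, COL4A1, COL5A1, ITGAV and ITGB6 were among those that rose there, and none of them was called higher with overexpression. ANKRD1 and CYR61, which rose with overexpression, fell in the knockdown. The arms differed at CTGF by 4.87 on the log2 scale, more than its 3.25 with overexpression, so its change in the knockdown was negative. Among 28 ATF4 targets 5 rose and 1 fell with overexpression (5 and 1 adjusted over the list alone), with camera at 0.0148 and adjusted p = 0.67 with an estimated correlation. Without control replicate 1, 15 rose and 1 fell, and the median log2 fold change moved from 0.32 to 0.68. That library stood at 0.26 in the mean of the list, centred over the 12 libraries, against -0.67 and -0.79 in the other controls. STC2 rose 2.64-fold, ATF5 2.67-fold and ATF4 1.54-fold, while DDIT4, an inhibitor of mTORC1, fell 2.54-fold. These 4 calls ended without a single library, with adjusted p-values up to 0.0759 for STC2 without control replicate 3, 0.119 for ATF5 and 0.112 for ATF4 without control replicate 2, and 0.0684 for DDIT4 without overexpression replicate 3.

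Besides glutathione metabolism, lists called lower included p53 targets, oxidative phosphorylation and extracellular matrix. Of 28 p53 targets 0 rose and 9 fell (2 and 12 adjusted over the list alone), with camera at 0.000656 and adjusted p = 0.581 with an estimated correlation. BTG2 fell 2.97-fold, SESN1 2.77-fold, the death receptor TNFRSF10B 1.62-fold and FAS 1.57-fold. Of 34 oxidative phosphorylation genes 1 rose and 11 fell (1 and 12 adjusted over the list alone), with camera at 1.02e-05 and adjusted p = 0.501 with an estimated correlation. COX6A1, SDHA and UQCRQ fell 1.40-fold, 1.34-fold and 1.73-fold, and NDUFA9 rose 1.40-fold. Of 13 mitochondrially encoded genes, which include further subunits of this chain, 2 rose, 0 fell and 11 did not pass (3 and 0 adjusted over the list alone). This list was called higher by camera at 0.0283, with adjusted p = 0.67 with an estimated correlation. Without knockdown replicate 2, 4 of its genes rose. The 2 lists were not tested against each other. Of 27 matrix and integrin genes 0 rose and 6 fell (1 and 9 adjusted over the list alone), with camera at 0.0147 and adjusted p = 0.501 with an estimated correlation. Without control replicate 1, 10 matrix and integrin genes fell, and without knockdown replicate 2, 11 of these and 15 oxidative phosphorylation genes fell. The integrin subunits ITGB1 and ITGAV fell 1.44-fold and 1.46-fold, the collagen COL6A1 1.69-fold and the laminin LAMA5 1.42-fold. Calls of FAS, NDUFA9, SDHA, UQCRQ, ITGB1, ITGAV, COL6A1 and LAMA5 ended without a single library. Adjusted p-values rose to 0.0501 for FAS and 0.0714 for UQCRQ without control replicate 3, 0.0554 for NDUFA9 and 0.0704 for SDHA without overexpression replicate 2, 0.0554 for ITGB1 and 0.0773 for LAMA5 without overexpression replicate 3. They were 0.0557 for ITGAV without overexpression replicate 1, and 0.054 for COL6A1 without control replicate 2. Leaving out 1 library moved the count of called genes from 2152 to 1226, 962 and 821 without overexpression replicates 1, 2 and 3. It moved to 946 and 933 without control replicates 2 and 3, and to 3300 without knockdown replicate 2. Without both control replicate 1 and knockdown replicate 2, a setting chosen after seeing the data, 4462 genes passed.

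The knockdown arm asks the opposite question, which transcripts change when NR0B1 is lowered. CBS, JUN and NFE2L2 fell, as did 12 of 28 ATF4 targets, and 13 of 27 matrix and integrin genes rose, though neither list was called with an estimated correlation (adjusted p = 0.747 and 0.724). CBS went from 97.0 ± 3.34 to 37.4 ± 11.4 CPM (2.59-fold lower, adjusted p = 0.00264), NFE2L2 from 337 ± 16.4 to 145 ± 37.7 CPM (2.32-fold, adjusted p = 0.00123) and JUN from 273 ± 23.3 to 117 ± 20.3 CPM (2.34-fold, adjusted p = 0.00268). The basement membrane collagen COL4A1 rose 2.37-fold, from 212 ± 33.3 to 504 ± 94.6 CPM (log2 fold change 1.25, SE 0.15, adjusted p = 0.000394). In all, 2851 genes passed, 1479 higher and 1372 lower, and 938 differed by 2-fold or more (593 higher and 345 lower), a count that ran from 612 to 1070 when each library was left out in turn and was 544 with limma. On log2(FPKM + 1) values limma called 2854 genes, of which 41.1% were higher, against 51.9% in the count fit.

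The serotonin receptor HTR1D was at 0 in the 3 knockdown libraries and at 5.69 ± 4.52 CPM in the control, at least 98.5-fold lower against a floor of 3 counts over the group. The glutamate transporter SLC1A3 fell from 13.8 ± 1.51 to 0.0820 ± 0.142 CPM and ANKRD1 from 66.7 ± 7.57 to 3.52 ± 3.08 CPM. SVEP1 and ITGBL1, both secreted or matrix proteins, fell 13.0-fold and 13.1-fold, and the small GTPase RAB39B fell 13.0-fold to 2.83 ± 1.85 CPM. NOP56 was also among the 8 largest falls, at 28.9 ± 17.6 against 0.511 ± 0.491 CPM, and is uncertain because its control values ran from 13.5 to 48.0 CPM. The protease inhibitor SPINK6 rose to 7.94 ± 1.39 from 0.209 ± 0.181 CPM (log2 fold change 5.2, SE 0.53). Of the other large rises, OAS2, TNFSF10, IFI6, IFIT1, CLEC4E and ISG15 had SDs above their means, since knockdown replicate 2 held nearly all of the signal. OAS2 stood there at 393 CPM against 0.876 and 0.676 CPM in replicates 1 and 3, and IFI6 at 461 against 1.49 and 1.97 CPM. Without that replicate, adjusted p was 0.445 for OAS2, 0.565 for IFI6, 0.237 for IFIT1, 0.114 for CLEC4E and 0.156 for ISG15. These 5 also lost their calls without any 1 of the knockdown controls, up to 0.0943 for IFI6 without replicate 3. TNFSF10, at 7.85 ± 12.1 against 0.0198 ± 0.0342 CPM, kept its call without knockdown replicate 2 (0.0282) and lost it without knockdown control replicates 1, 2 and 3 (0.0561, 0.0602 and 0.0617).

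Of 30 interferon response genes 14 rose and 0 fell in the knockdown (24 and 0 adjusted over the list alone), with camera at 0.00138 and adjusted p = 0.769 with an estimated correlation. Without knockdown replicate 2, 2 rose and 2 fell, and the median log2 fold change moved from 4.03 to 0.10. When only the 6 libraries of the arm were fitted, and with limma, 0 rose and 0 fell. MX1 showed 5.21, 640 and 2.71 CPM in knockdown replicates 1 to 3 and between 1.58 and 2.84 CPM in the control. OAS1 and OAS3 kept their calls without that replicate, at log2 fold changes of 1.22 and 0.91 in place of 4.15 and 3.14, but lost them without any 1 of the knockdown controls (adjusted p up to 0.0726 and 0.0905, both without replicate 3). The list was in the same high range in the overexpression arm, where all 6 libraries lay above the mean of the 12, and 0 of its 30 genes passed in that arm's own comparison. Without knockdown replicate 2, 4 were higher with overexpression, and without both that library and overexpression control replicate 1, 24 were higher and the median log2 fold change moved from 0.57 to 1.10.

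**Figure D3:**
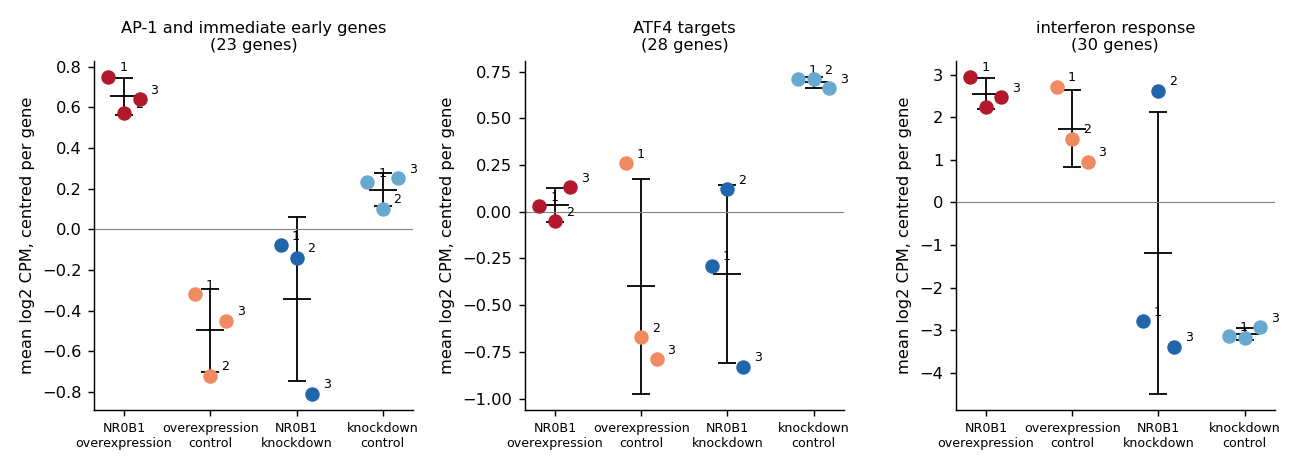
Mean log2 CPM of the members of 3 fixed gene lists, centred per gene over the 12 libraries (vertical axes), with dots numbered by replicate and bars for mean and SD. Interferon genes stand at 2.62 in knockdown replicate 2 and at -2.79 and -3.38 in replicates 1 and 3, and ATF4 targets stand between 0.66 and 0.71 in the knockdown control.

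Of the 11 study focus genes 0 rose and 4 fell in the knockdown, and adjusted over the list alone 1 rose and 5 fell. The 4 were NR0B1 itself, CBS, JUN and NFE2L2. NR0B1 is the target of the knockdown, and the others were listed because the study followed them up. The count is thus no independent evidence of direction. KEAP1, SLC7A11, GPX4, GCLC, GCLM, GSS and GSR did not pass, with GPX4 at 121 ± 4.4 against 125 ± 16.6 CPM (log2 difference -0.04, and 0.04 without knockdown control replicate 1) and SLC7A11 at 449 ± 67.4 against 545 ± 92.0 CPM. GCLC stood at a log2 difference of -0.51 and passed without knockdown replicate 3 (-0.75, adjusted p = 0.0121). GCLM went the other way, at 0.56, and passed without knockdown replicate 2 (0.68, adjusted p = 0.0356). Of 43 glutathione metabolism genes 8 rose and 1 fell (8 and 1 adjusted over the list alone), and camera did not call the list (adjusted p = 0.182). When the 6 libraries of the arm were fitted alone 4 rose and 1 fell. Without knockdown replicate 2, 13 of these rose and 1 fell, as did 8 and 1 of the ferroptosis suppressors and 8 and 2 of the NRF2 targets. The thioltransferase GSTO1 rose 1.89-fold, GPX1 1.44-fold, MGST2 1.70-fold and GPX8 1.46-fold. Of 30 ferroptosis suppressors 5 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.532), with HSPB1 up 2.74-fold to 321 ± 59.9 CPM, the uncertain AKR1C3 up 1.69-fold, CD44 up 1.43-fold, MBOAT2 and AKR1C1 up by 1.06 and 0.93 on the log2 scale, and NFE2L2 down. Of 27 ferroptosis drivers 4 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.366), namely the metalloreductase STEAP3 (1.70-fold), SLC11A2 (1.64-fold), ACSF2 (1.82-fold) and SAT1 (1.89-fold). Calls of CD44 (0.0505 without knockdown control replicate 3), ACSF2 (0.063 without knockdown control replicate 2) and SAT1 (0.161 without knockdown replicate 2, and above 0.05 without 10 of the 12 libraries in turn) ended. Of 37 NRF2 targets 4 rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.697), with CBR3 up 3.65-fold and the cytochromes CYP4F3 and CYP4F11 down 2.45-fold and 2.05-fold, the last losing its call without knockdown replicate 1 (0.0565). Over all genes tested 23.9% were called in the knockdown. The glutathione, ferroptosis suppressor, ferroptosis driver and NRF2 lists each had a smaller share of called members.

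ATF4 targets, genes of the amino acid response, fell in the knockdown: 0 of 28 were higher and 12 lower (0 and 18 adjusted over the list alone), with camera at 2.63e-07 and adjusted p = 0.747 with an estimated correlation; 18 were lower without overexpression control replicate 1, and as many without knockdown replicate 2. STC2 fell 4.50-fold to 58.7 ± 19.5 CPM, the serine synthesis enzyme PHGDH 1.99-fold, and the tRNA synthetases GARS and AARS 2.33-fold and 2.15-fold. Of 23 AP-1 and immediate early genes 4 rose and 10 fell (4 and 11 adjusted over the list alone), with camera at 0.00785 and adjusted p = 0.724 with an estimated correlation. The phosphatase DUSP1 fell 2.92-fold, MYC 2.64-fold and ATF3 7.15-fold, while FOSB and EGR3 were called higher with most of their signal in knockdown replicate 1 (FOSB at 35.8 CPM there against 5.77 and 4.12 CPM, adjusted p = 0.0522 without it; EGR3 at 2.47 against 0.429 and 0.43 CPM, adjusted p = 0.178). The other members called higher were FOS and DUSP4, at log2 fold changes of 2.13 and 0.54, and 0 members were called higher when the 6 libraries of the arm were fitted alone. FOSB also lost its call without knockdown control replicates 1 and 2 (0.0732 and 0.0767), and EGR3 without knockdown controls 1 to 3 (0.102, 0.0618 and 0.115). Of 27 matrix and integrin genes 13 rose and 0 fell (16 and 0 adjusted over the list alone), with camera at 1e-06 and adjusted p = 0.724 with an estimated correlation. Besides COL4A1, COL4A2 rose 2.03-fold, the integrin subunit ITGB3 2.66-fold and tenascin C, TNC, 5.02-fold.

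Of 24 cholesterol synthesis genes 10 rose and 0 fell (10 and 0 adjusted over the list alone), with camera at 0.00785 and adjusted p = 0.769 with an estimated correlation. In the mean of the list, centred over the 12 libraries, knockdown replicates 1 and 3 stood at 0.41 and 0.33. Knockdown replicate 2 stood at -0.27, within the -0.36 to -0.23 of the knockdown control, and thus showed no rise. SREBF2, the transcription factor of this pathway, rose 1.40-fold, INSIG1 2.74-fold and the sterol carrier STARD4 2.24-fold. INSIG1 and STARD4 lost their calls without knockdown control replicate 1 (adjusted p = 0.0619 and 0.051), and STARD4 also without knockdown control replicate 3 (0.0529). Of 16 histone genes 0 rose and 6 fell (0 and 7 adjusted over the list alone), with camera at 0.000744 and adjusted p = 0.724 with an estimated correlation; only 1 fell when the 6 libraries of the arm were fitted alone. HIST1H2AC fell 2.15-fold, HIST1H1C 2.34-fold, HIST1H2AE 4.31-fold and HIST1H1E 2.11-fold, and members of this family are uncertain because their sequences are alike. The last 3 lost their calls without a single library (adjusted p up to 0.0741 for HIST1H1C without knockdown control replicate 1, and 0.0731 for HIST1H1E and 0.0845 for HIST1H2AE without knockdown control replicate 3). The count of 2851 called genes moved to 1708, 1897 and 1503 without knockdown control replicates 1, 2 and 3 and to 1833 when only the 6 libraries of this arm were fitted. Without both overexpression control replicate 1 and knockdown replicate 2 it was 4493.

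The 2 arms change NR0B1 in opposite directions, each against its own control. The response differed between the arms for 3054 genes, 1557 with the larger fold change in the overexpression arm and 1497 with the smaller. This tests the difference and does not require opposite movement. On log2(FPKM + 1) values limma called 3024 genes. Of these 60.1% had the larger fold change in the overexpression arm, against 51.0% in the count fit. Of the genes called in both arms 490 went in opposite directions, where independent lists would share 256.7, and 199 went in the same direction, where 258.5 would be shared. The former count ran from 197 to 784 when each library was left out in turn and was 759 with DESeq2. Without knockdown replicate 2, 606 went in opposite directions (476.4 for independent lists) and 529 in the same direction (475.5), so the shortfall of the latter was not kept. Of the 490, 270 were higher with overexpression and lower in the knockdown and 220 the reverse. Besides ANKRD1 and NOP56, they included the vascular peptide ADM, which rose 4.26-fold and fell 3.87-fold, CYR61, which rose 3.71-fold and fell 6.45-fold, and KLF2, which rose 3.64-fold and fell 3.49-fold. ADAMTS7 fell 3.57-fold with overexpression and rose 3.56-fold in the knockdown, SLC52A1 fell 6.48-fold and rose 5.42-fold, and TCN1 fell 5.08-fold and rose 5.22-fold. Genes called higher in both arms included the hyaluronan synthase HAS2 (7.76-fold and 8.89-fold), EGR3, FOSB and SPINK6, the last at 0.314 ± 0.0299 CPM with overexpression against a control at 0, at least 5.16-fold higher against a floor of 3 counts over the group. SLC52A1, TCN1 and HAS2 lost their calls in either arm without a single library. Adjusted p reached 0.129, 0.104 and 0.106 in the overexpression arm, without control replicate 3, overexpression replicate 2 and control replicate 3. It reached 0.121, 0.0936 and 0.0891 in the knockdown, without knockdown control replicates 3, 3 and 2. The log2 fold change of TCN1 with overexpression went from -2.34 to -1.43 without overexpression control replicate 1 (adjusted p = 0.0876). In the knockdown that of TCN1 went from 2.39 to 1.67 without knockdown replicate 2 (adjusted p = 0.0685). Across the 11908 genes, which are not independent replicates, the fold changes of the arms had a Pearson r of -0.056 and a Spearman rho of -0.11. Without overexpression control replicate 1 and knockdown replicate 2 these were 0.027 and -0.013, so the weak negative relation was not kept. In the same setting 1026 genes went in opposite directions (841.3 for independent lists) and 874 in the same direction (842.3).

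The control groups differed from each other at 3973 genes, 2051 higher and 1922 lower in the overexpression control, and 1328 of them by 2-fold or more. The count fell to 1225 with a replicate block and to 2560 without knockdown control replicate 3. limma on log2(FPKM + 1) called 4131 genes, 40.2% of them higher, against 51.6% in the count fit. Of 30 interferon response genes 26 were higher in the overexpression control and 0 lower, with a median log2 difference of 4.72; 17 were higher without overexpression control replicate 1. Of the 490 genes called in opposite directions, 428 differed between the controls against the direction of NR0B1, 1 with it, and 61 did not pass. The calls in the arms use the same control libraries, which favours a difference in this direction, so these counts are no test of it. CBS was lower in the overexpression control than in the knockdown control (log2 difference -2.02, SE 0.24), as were JUN (-2.47, SE 0.22), NFE2L2 (-0.76, SE 0.18), ANKRD1 (-3.72, SE 0.56) and CYR61 (-2.58, SE 0.41), while NR0B1 was higher there. JUN thus stood at 49.3 ± 16.9 CPM in the overexpression control and 117 ± 20.3 CPM in the knockdown, and at 284 ± 11.9 CPM with overexpression and 273 ± 23.3 CPM in the knockdown control.

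**Figure D4:**
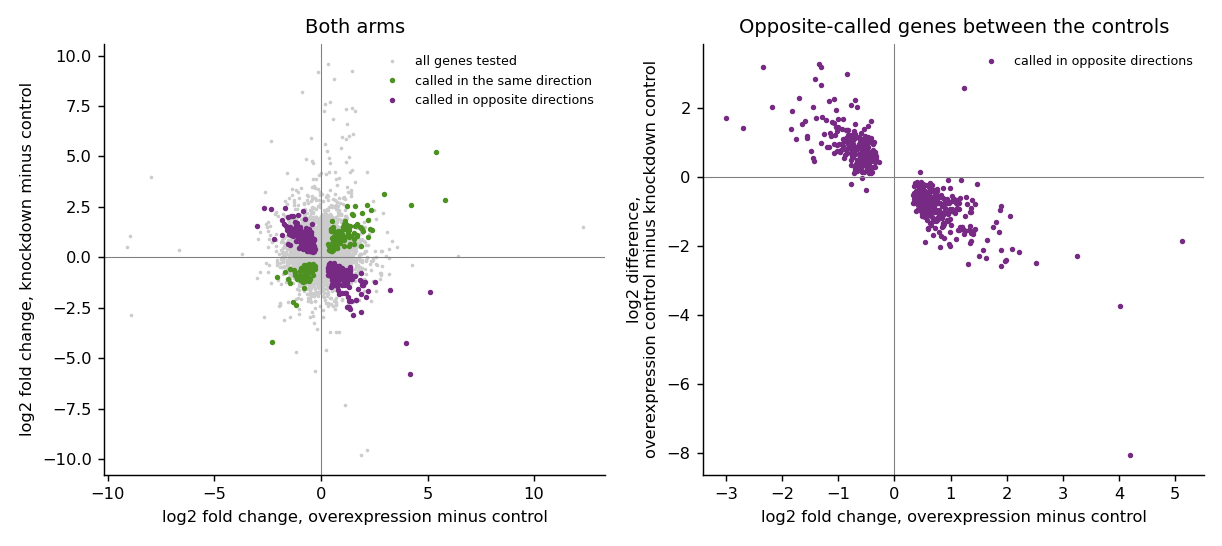
Left, log2 fold change of each of the 11908 genes with overexpression (horizontal axis) and in the knockdown (vertical axis), with the 490 genes called in opposite directions in purple and the 199 called in the same direction in green. Right, the 490 genes with the log2 difference between the control groups on the vertical axis; both axes of this panel use the overexpression control libraries, and 428 of the genes differed between the controls against the direction of NR0B1.

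RNA of other cell types was read from marker lists. All 8 endothelial markers stayed below 1 FPKM in every library, the highest being PECAM1 at 0.23 FPKM. Of 10 fibroblast markers only COL1A1 and THY1 reached 1 FPKM, with COL1A1 at means of 14.3 FPKM in the knockdown and 3.13 FPKM in its control. Among 12 blood and immune markers CD14 (up to 4.46 FPKM) and CD68 (up to 59.6 FPKM) reached 1 FPKM, and PTPRC did not exceed 0.01 FPKM. CD14 was called lower with overexpression and higher in the knockdown (log2 fold changes -1.42 and 2.04), the former call ending without overexpression replicate 2 (adjusted p = 0.074). COL1A1 also counts among the matrix genes that rose in the knockdown, a call that ended without knockdown replicate 1 (adjusted p = 0.0758), and COL1A2, COL3A1 and DCN stayed below 1 FPKM in all libraries.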

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

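Tests chosen only after the result was seen were those of both patterns weighed here, the assembled transcripts as features, and the counts over other splits. The assembled transcripts, left out of the gene values, were tested as features of their own: 416 of 4742 passed with overexpression (268 higher and 148 lower) and 388 in the knockdown (231 higher and 157 lower). They stand here because no comparison of genes uses them.

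Interferon genes were high in knockdown replicate 2 and low in knockdown replicates 1 and 3 and in the knockdown controls, and 7 of the 12 libraries lay above the middle of the range. NR0B1 knockdown alone as the cause is opposed by the level of NR0B1, at 3.31 CPM in replicate 2, between 2.99 and 5.84 CPM in replicates 1 and 3. RNA of the overexpression arm, or a library of that arm under a wrong label, is also opposed by NR0B1, which was at 17.9 CPM or more in all libraries of that arm. With the lowest of these as the source, its mixing share in replicate 2 was -0.08. Over 10000 resamples of genes the 47 genes lower in that arm gave a median share of 0.26 (95% interval -0.02 to 0.50), the 191 other genes higher there 0.49 (0.36 to 0.60) and the 30 interferon genes 1.34 (1.11 to 1.47). Genes of 1 library are not independent, so these intervals do not measure the spread between libraries. The genes were picked by a gap between knockdown replicates 1 and 3 and the source, which favours shares toward the source. A first bound on these shares, under 0.5 for the 47 genes, was met by the median but not by its interval and did not decide; the test on NR0B1 was chosen last, after these values were seen. Replicate 2 thus lay toward the overexpression arm over many genes, and it correlated more with overexpression control replicate 2 (0.934) than with knockdown replicates 1 and 3 (0.923 and 0.9). A difference in handling or culture could account for the pattern and this wider shift, and cannot be told apart from other causes, since the labels give no batch or day.

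Overexpression control replicate 1 stood apart from control replicates 2 and 3. RNA of the overexpression group might account for it, but NR0B1 was at 17.9 CPM there, below 60.1 and 55.2 CPM. The shares that go toward the overexpression group were 0.24 (95% interval 0.16 to 0.37) for 87 other genes higher, 0.57 (0.42 to 0.67) for 30 other genes lower and 0.77 (0.54 to 0.97) for 7 interferon genes. All 3 go toward that group, but a single source would give 1 share, and the first lies below the others. The intervals in this paragraph also rest on resampled genes of 1 library. These genes were picked by a gap between control replicates 2 and 3 and the source, which favours shares toward the source. RNA of the knockdown arm as the whole cause is opposed by a median share of -1.29 (-2.0 to -0.91) over interferon genes, which lay above, not below, the other controls. The low NR0B1 goes with it, as does the share of 0.18 (0.12 to 0.42) over 75 other genes higher in that arm, while 126 genes lower there gave -0.06 (-0.21 to 0.17), so a small share stays open. Other differences between cultures stay open and were not tested.

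For the comparisons of 6 libraries the 10 splits are too few for a share under 0.05. With overexpression 2152 genes passed against 1 in the highest other split, and 565 against 1 at 2-fold or more. In the knockdown these counts were 2851 against 1 and 938 against 1, and between the controls 3973 against 0. In each of these 1 split, the real one, gave a count as large. camera's preset correlation gave unadjusted p of 0.00468 for glutathione metabolism with overexpression, against 9.59e-06 in another split (3 of 10 splits as small), and 0.0808 in the knockdown, against 0.0132 (3 of 10). For ferroptosis suppressors these were 0.195 against 3.31e-06 (8 of 10) and 0.414 against 0.104 (7 of 10). Lists called numbered 14 with overexpression against 17 in another split (4 of 10) and 8 in the knockdown against 15 (9 of 10), so regrouped libraries gave as many list calls as the real groups. Over 100 splits of both arms the real grouping gave 3054 genes whose response differed, against 2036 in the highest other split. That split was the real one with the knockdown arm mirrored, and further splits gave 0 to 557. Splits that mix treated and control libraries widen the spread within groups, which pushes their counts down. They therefore do not test whether the 3054 genes arose by chance. For the 490 genes called in opposite directions the highest other count was 199, in the mirrored split. Every further split gave 0, so the splits do not test the direction either.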

How the results depend on the processing

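The test chosen only after the result was seen was the omission of both libraries that stand apart, besides assembled transcripts as features. For all changes below the cause was not tested, unless fewer genes or libraries were fitted. Without both overexpression control replicate 1 and knockdown replicate 2, 4462 genes passed with overexpression, 4493 in the knockdown, 1040 with overexpression at 2-fold or more, 4590 for the difference of the arms, and 1026 went in opposite directions. In the same setting glutathione metabolism was lost with overexpression (adjusted p = 0.192), ferroptosis suppressors turned from lower to higher (0.907), GSR stood at 0.03, and 13 lists were called in the knockdown. Fitting only the 6 libraries of a comparison gave 1833 genes in the knockdown and 315 in opposite directions, and DESeq2 gave 759 of the latter. At 2-fold or more, limma, the stricter filter and quantile normalization gave 348, 305 and 358 genes with overexpression and 544, 483 and 522 in the knockdown. NR0B1 with overexpression was at a log2 fold change of 1.15 with limma and 1.0 with DESeq2, both past the threshold (0.0452 and 0.0415). With an estimated correlation glutathione metabolism was at 0.501 and lists called fell to 0 in both arms. With the replicate number as a replicate block 1225 genes differed between the controls. Deviations from the group means were correlated between same-numbered treated and control libraries. The values were 0.2, 0.13 and 0.01 in the overexpression arm and -0.01, -0.09 and -0.06 in the knockdown arm. Overexpression replicates 1 and 2 correlated best with the control of their own number, and no knockdown replicate did. These weak values show no pairing in the knockdown arm and leave it open in the overexpression arm.

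Leaving out each library in turn gave 821 to 3300 genes with overexpression and 1503 to 3435 in the knockdown, 344 to 893 and 612 to 1070 at 2-fold or more, 2127 to 3785 for the difference of the arms, 2560 to 4920 between the controls and 197 to 784 in opposite directions. NR0B1 ranged from 0.62 to 1.27 with overexpression and from -2.42 to -1.87 in the knockdown. Glutathione metabolism ranged from 0.00427 to 0.2 with overexpression and 0.0527 to 0.397 in the knockdown, and ferroptosis suppressors from 0.0575 to 0.95, reversed at the last, and 0.401 to 0.845. Lists called ranged from 9 to 19 and 6 to 12. GSR with overexpression ranged from -0.24 to 0.03 and GPX4 in the knockdown from -0.14 to 0.04. Over named genes, 1211 of 1327 values under the alternatives fixed beforehand kept direction and side of the threshold, 103 lost it, 13 gained it and 0 reversed; leaving out libraries, 1421 of 1644 kept it, 213 lost it, 8 gained it and 2 reversed. These pooled values include genes that were not called. Of the called named genes, 30 of 61 with overexpression and 41 of 65 in the knockdown kept the call whichever library was left out. The other 31 and 24 lost it without at least 1 library. Depth limits genes under the floor of 0.155 to 0.235 CPM.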

Other observations

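Tests chosen only after the result was seen were the pathways, the omission of both overexpression control replicate 1 and knockdown replicate 2, and the test in held-out controls; the lists were fixed before the data were examined. With overexpression 3 of 11 Wnt targets rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.0283, and adjusted p = 0.501 with an estimated correlation), and 4 of 16 heat shock genes rose and 1 fell (5 and 1 adjusted over the list alone; 0.03, and adjusted p = 0.67 with an estimated correlation). Cytosolic ribosomal protein genes were called lower (0 higher and 4 lower of 33; 0 and 1 adjusted over the list alone; 0.00039, and adjusted p = 0.67 with an estimated correlation). Of the 33, 11 were lower without overexpression control replicate 1, 15 without knockdown replicate 2 and 26 without both. Also called lower were unfolded protein response genes (0 and 4 of 21; 0 and 5 adjusted over the list alone; 0.0283, and adjusted p = 0.501 with an estimated correlation) and drug metabolism genes (1 and 5 of 26; 2 and 8 adjusted over the list alone; 0.0147, and adjusted p = 0.501 with an estimated correlation; 8 lower without knockdown replicate 2). NF-kB and inflammatory cytokine genes were called lower as well (0 and 2 of 26; 0 and 0 adjusted over the list alone; 0.0283, and adjusted p = 0.684 with an estimated correlation), with 9 lower without knockdown replicate 2 and 0 without overexpression control replicate 1. Of the lists that rose, 6 Wnt targets were higher without overexpression control replicate 1 and 7 heat shock genes without knockdown replicate 2. In the knockdown 5 Wnt targets rose and 1 fell (6 and 1 adjusted over the list alone; 0.0326, and adjusted p = 0.724 with an estimated correlation) and 5 unfolded protein response genes rose and 1 fell (8 and 1 adjusted over the list alone; 0.0326, and adjusted p = 0.724 with an estimated correlation). With camera on log2 CPM the call of the unfolded protein response genes in the knockdown was lost (adjusted p = 0.0507). Of 16 heat shock genes 5 rose in the knockdown and 0 fell (6 and 0 adjusted over the list alone). That list was not called there by camera (adjusted p = 0.0515). Of 24 proliferation genes 0 passed with overexpression and 2 rose in the knockdown (0 and 0 adjusted over the list alone). Without knockdown replicate 2, 9 rose there, and without both of those libraries 19 rose, with the median log2 fold change at 0.45 in place of 0.22.

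Of 279 pathways in the authors' annotation, camera called 5 higher and 38 lower with overexpression and 6 higher and 4 lower in the knockdown, and 0 with an estimated correlation. Spliceosome genes were higher with overexpression (adjusted p = 5.18e-05, and adjusted p = 0.541 with an estimated correlation), and ECM-receptor genes were lower (0.00089, and adjusted p = 0.5 with an estimated correlation) and higher in the knockdown (6.4e-05, and adjusted p = 0.929 with an estimated correlation). Of the HEK293 markers NEFL, INA, SOX2 and ZIC2 were at 1 FPKM or more in all 12 libraries, while NEFM, PAX2 and NELL1 stayed below 1 FPKM. Of the 5 that were tested, INA rose with overexpression, and NEFL, INA and SOX2 rose in the knockdown and 0 fell (3 and 1 adjusted over the list alone), with a median log2 fold change of 0.73 and camera at 0.171. In the knockdown the calls of NEFL and INA ended without knockdown control replicates 3 and 1 (adjusted p = 0.0662 and 0.0649). No explanation was tested.

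A hypothesis for the 490 genes called in opposite directions is that NR0B1 abundance alone sets their level in all 4 groups. NR0B1 was higher in the overexpression control than in the knockdown control, so most of these genes should then differ between held-out controls in its direction. Only 6 of 9 pairs of held-out control libraries, those without overexpression control replicate 1, differed in NR0B1 by 2-fold or more. For these pairs, fits of the remaining libraries over all genes tested called between 78 and 91 genes in opposite directions. Between 1.3% and 3.7% of them differed with NR0B1 in the held-out pair, which is against the hypothesis for those genes. How many of them belong to the 490 was not counted, and these 6 fits all kept overexpression control replicate 1. Another difference between the arms could account for the genes called in opposite directions and was not tested.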
